A study of Mus musculus with 6 samples.

How the data were processed

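RNA sequencing of mouse submandibular salivary glands was deposited as a table of FPKM (fragments per kilobase of exon, scaled to the number of mapped fragments) for 6 libraries: 2 unirradiated controls and 2 each at 6 h and 24 h after 5 Gy. The deposited FPKM values were used as they stand; per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to mm10 and FPKM computed with Cufflinks 2.2.1. Of 24421 table entries, 27 whose gene symbol had become a date number were left out, since the symbol could not be recovered. The other 24394 had a symbol each and no symbol was repeated. Gene positions, types and exon lengths were taken from GENCODE release M21 (GRCm38, the assembly also called mm10; positions counted from 1), matched by symbol for 11272 of the tested genes (96.6%).

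In the control and 6 h columns, 99.01% of 17475 genes had values on steps of whole reads (relative tolerance 1e-06), and the steps give library sizes of 12340000, 11830000, 12130000 and 12580000 reads. A single read in a gene of 2 kb was worth 0.0405, 0.0423, 0.0412 and 0.0398 FPKM in these libraries, in the order control 1 and 2, 6 h 1 and 2. In the 24 h columns 99.99% of values had at most 6 digits, no steps were found and the depth is unknown, which points to another quantification route for these columns. The notes name 1 pipeline only, and which of the 2 forms of values it gave was not tested. FPKM summed to 879169.6 and 886232.8 in control, 900281.4 and 866233.0 at 6 h, and 677320.3 and 1203217.8 at 24 h. Spt1 alone held 25.78 and 25.72% of the sum in control and 28.19 and 22.77% at 6 h, while the top genes at 24 h were Scgb2b26 with 12.98% and Scgb1b27 with 31.37%. Of genes at 0 in both 24 h libraries, 159 had a mean of at least 1 FPKM over the other 4, 112 of them microRNA or snoRNA genes, and 91 genes at 0 in the other 4 libraries had a mean of at least 1 FPKM at 24 h. No fold change is given for a gene that all libraries of one route listed under 0.2 FPKM, with the 4 control and 6 h libraries taken as one route; the limit was chosen after values were seen. A gene under it at 6 h but not in control, such as Lck, kept its fold change.

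Values were transformed as log2(FPKM + 1), which shrinks fold changes of low genes toward 0. Genes with a mean of at least 1 FPKM over the 6 libraries were kept (11674), and limma 3.58.1 in R 4.3.3 fitted a mean per group with empirical Bayes moderation and a trend. Tests were two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05; 3 residual degrees of freedom were available. The comparisons were 6 h against control, 24 h against control and 24 h against 6 h. Values after ± are the SD of 2 libraries for FPKM and the SE of the fit for log2 fold changes. The labels do not state separate animals, so the tests measure the spread between these samples. Genes changed at 6 h and at 24 h were compared by a count of shared calls, set beside independent lists and 100 simulations of unchanged groups, and by time course classes (transient, sustained, late) resting on the tests between the 3 groups.

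There were 33 gene lists of response programmes and cell type markers; those with at least 5 tested members (26) were tested with camera at a correlation between genes of 0.01, adjusted over the lists of a comparison, again with an estimated correlation, and with fry, which tests whether the members of a list move one way on balance. Mitochondrially encoded genes were not analysed here. For lists with 2 to 4 tested members only values are given: the median log2 fold change at 6 h and 24 h against control was 0.78 and 1.75 for neutrophil, -0.03 and 0.66 for B cell, 0.06 and 0.43 for Schwann cell and neuron, 0.67 and 1.51 for neighbouring gland, -0.06 and 0.52 for erythrocyte and 0.03 and 0.33 for sex-linked genes. The genes named were, per comparison, the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change. Libraries of the groups could not overlap, the higher group had a mean of at least 1 FPKM, and unnamed or short RNA models were left out. Also named were the 3 members with the smallest p of each list with a camera call or at least 2 called genes, and Cdkn1a, Mdm2, Bax, Bbc3, Phlda3, Ccng1, Aqp5, Chrm3, Mki67 and the sex-linked genes. Genes named outside this rule are said to be so, or are named for their share of the FPKM sum, and some that the rule picks are not reported here. Groups, comparisons, tests, lists and this rule were fixed before the data were examined.

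Data were simulated from the mean of each gene over all libraries, 24 h included, and the residual spread of the fit. In 10 simulations, 200 genes were changed in the 6 h group of each. For 6 h against control, the fit recovered 61.8% of genes changed by a log2 value of 1 and 88.6% of those changed by 2. Of its calls 4.6% were false. The slope of estimated on true change was 1, and 10 changed and 0 unchanged lists were called. Genes were drawn independently of each other and changed lists held raised genes only, so this does not test camera on correlated genes. Alternatives varied the pseudocount, filter, scaling (median-of-ratios factors, quantile normalization), groups in the fit, variance model, library weights, replicate block, threshold and each library left out in turn. Those added after seeing the data left out control replicate 1 with 24 h replicate 2, kept genes above 0 in every group, or removed a trend with exon length. With 2 libraries per group, tests of single outlying libraries and of other splits were not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the depth checks, annotation and figures.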

Results

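The series measured gene expression by RNA sequencing in the submandibular salivary gland, a mixed seromucous gland below the jaw, of wild-type C57BL/6 mice. Glands were sampled without irradiation (control) and at 6 h and 24 h after 5 Gy of ionizing radiation, with 2 libraries in each of the 3 groups. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples. The control and 6 h values lay on steps of whole reads. Together with exon lengths, these steps put library sizes near 12340000 and 11830000 reads (control) and 12130000 and 12580000 reads (6 h). The 24 h values had no such steps and their depth is unknown. Y-linked genes were present in all 6 libraries, with Ddx3y at 10.3 ± 2.31, 11 ± 0.299 and 13.1 ± 2.97 FPKM (SD, n = 2) in control, 6 h and 24 h glands. Eif2s3y was at 24.7 ± 3.95, 28.1 ± 0.624 and 33.6 ± 3.71 FPKM in the same order, and Kdm5d and Uty at 4.08 and 4.62 FPKM in control. Xist, expressed from the inactive X chromosome of females, was at 0.0140, 0.0159 and 0.212 FPKM.

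Several genes of neighbouring tissue varied between libraries of one group. Muc19, a mucin of the sublingual gland, was at 0.0178 and 178 FPKM in control replicates 1 and 2, 139 and 160 FPKM at 6 h, and 2.25 and 149 FPKM at 24 h. Amy1, an amylase abundant in the parotid gland, was at 18.4 and 2945 FPKM in control, 24.4 and 5662 FPKM at 6 h, and 1612 and 17032 FPKM at 24 h. Adipoq, an adipocyte hormone, was lower in replicate 1 of control and of 6 h (1.18 and 2.07 FPKM) than in replicate 2 (28.0 and 24.8 FPKM), and at 24 h was at 28.1 FPKM in replicate 1 and 13.7 FPKM in replicate 2. The epidermal keratin gene Krt10 and the B cell gene Ms4a1 were highest in replicate 2 of 24 h (129 and 2.82 FPKM). These genes were chosen after their values were seen. The gaps in Amy1 within every group, and in Muc19 within control and 24 h, argue against repeat libraries of the same RNA. Whether the glands came from separate animals stays open.

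**Figure D1:**
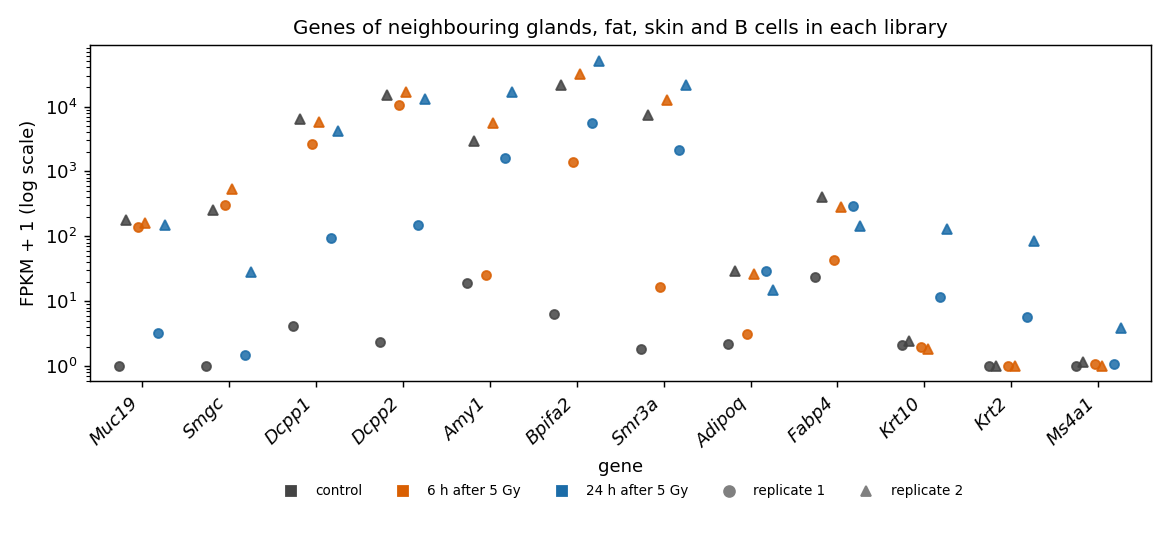
FPKM + 1 on a log axis for secretory genes of salivary glands (Muc19 to Smr3a), fat (Adipoq, Fabp4), skin (Krt10, Krt2) and B cells (Ms4a1), 1 point per library, colours by group and symbols by replicate number; the genes were chosen after their values were seen. Control replicate 1 had Muc19 at 0.0178 FPKM and control replicate 2 at 178 FPKM.

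The first comparison asked which genes differed 6 h after irradiation. Targets of the transcription factor p53 were higher at 6 h, clock genes moved in both directions, and the MHC class II genes H2-Ab1 and H2-DMb1 were lower. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 42.2 ± 3.50 FPKM at 6 h against 2.24 ± 0.164 FPKM in control (SD, n = 2), a log2 fold change of 3.73 ± 0.10 (SE). Gdf15, a secreted stress cytokine, had the highest log2 fold change of the named genes, 5.57 ± 0.15, with 70.9 ± 14.5 FPKM against 0.497 ± 0.0689 FPKM. Of 11674 genes tested with limma, 81 were higher and 37 lower at an adjusted p under 0.05, and 63 and 19 of these changed at least 2-fold. The unadjusted p was under 0.05 for 1724 genes.

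Of the 36 p53 target genes tested, 19 rose, 0 fell and 17 did not pass; adjusted over the list alone, 28 were higher and 2 lower. Their median log2 fold change was 1 and the camera adjusted p was 2.51e-34. With an estimated correlation the adjusted p was 0.0222. Fry called this list alone at 6 h (adjusted p = 0.000376). Ccng1, a cyclin of the damage response, rose from 40.6 ± 0.262 to 224 ± 4.85 FPKM (adjusted p = 0.00036), and the death gene Bax from 15.7 ± 3.37 to 70.6 ± 8.73 FPKM (adjusted p = 0.00529). Aen, an apoptosis-enhancing nuclease, and Eda2r, a TNF receptor family member, rose by 2.54 ± 0.14 and 2.52 ± 0.12 on the log2 scale. Phlda3, an inhibitor of Akt, rose by 1.92 ± 0.11 and Mdm2, the ubiquitin ligase of p53, by 1.10 ± 0.10 (adjusted p = 0.0021 and 0.0103). With control replicates 1 and 2, 6 h replicates 1 and 2, and 24 h replicates 1 and 2 left out in turn, the adjusted p of Mdm2 was 0.0685, 0.0587, 0.121, 0.103, 0.0532 and 0.052. That of Bax was 0.0151, 0.0197, 0.0635, 0.073, 0.066 and 0.064 in the same order, and Aen was at 0.0516 without 6 h replicate 2. Bbc3, which encodes the death protein PUMA, had a log2 fold change of 0.73 ± 0.18 that did not pass (adjusted p = 0.17). In GRCm38, the Cdkn1a gene lies at chromosome 17, 29090976 to 29100727, Gdf15 at chromosome 8, 70629393 to 70632456, Ccng1 at chromosome 11, 40748552 to 40755311 and Bax at chromosome 7, 45461697 to 45466898, and all are annotated as protein coding.

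**Figure D2:**
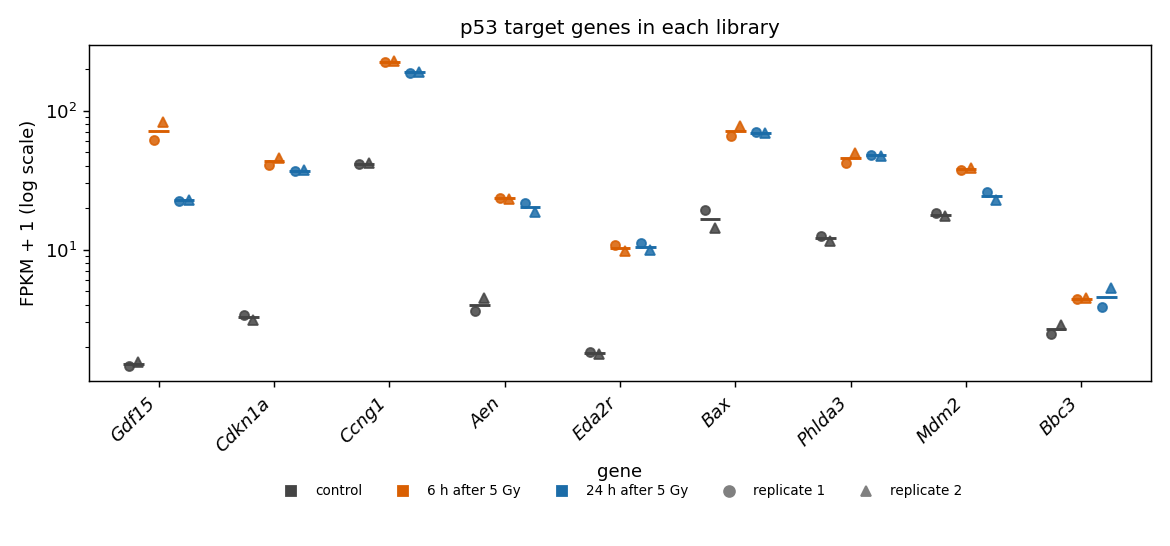
FPKM + 1 on a log axis for 9 p53 target genes in the 6 libraries, with a short line at the geometric mean of FPKM + 1 of each group. Cdkn1a was at 2.24 FPKM in control, 42.2 FPKM at 6 h and 35.9 FPKM at 24 h (means, n = 2).

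Of the 18 circadian clock genes, 6 rose and 2 fell at 6 h (adjusted over the list alone, 10 and 4). The median log2 fold change was 0.82 and the camera adjusted p 0.000213, with an adjusted p = 0.646 with an estimated correlation. Dbp, a clock output transcription factor, rose from 2.47 ± 0.0654 to 50.2 ± 11.4 FPKM, Tef by 2.04 ± 0.14 and Ciart by 2.02 ± 0.14 on the log2 scale. Arntl, which encodes the clock activator BMAL1, fell from 10.8 ± 1.10 to 0.417 ± 0.0287 FPKM (adjusted p = 0.00172), and Npas2, a paralog of Clock, fell with a log2 fold change of -1.85 ± 0.16 (adjusted p = 0.00745). Without 6 h replicates 1 and 2 in turn, the adjusted p was 0.0652 and 0.0547 for Ciart, 0.0564 and 0.0516 for Tef, and 0.048 and 0.0516 for Arntl. That of Npas2 was 0.0629 and 0.0555 without control replicates 1 and 2, and 0.0758 and 0.073 without 6 h replicates 1 and 2. The hours of day at which glands were collected are not given in the sources used here.

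Of the 16 inflammatory cytokine and NF-kB genes, 2 rose and 0 fell (6 and 0 adjusted over the list alone), and the camera adjusted p was 0.000156, with an adjusted p = 0.646 with an estimated correlation. Relb and Nfkb2, subunits of the noncanonical NF-kB complex, rose by 2.21 ± 0.25 and 1.09 ± 0.10 on the log2 scale. The adhesion gene Icam1 had a log2 fold change of 1.65 ± 0.32 that did not pass (adjusted p = 0.0957). In the glucocorticoid and systemic stress response list of 16 genes, 2 rose (4 higher and 1 lower adjusted over the list alone). Lcn2, which encodes an iron-binding protein of innate immunity, rose by 1.36 ± 0.09. Ddit4, an inhibitor of mTOR signalling that is also a p53 list member, rose by 0.95 ± 0.13. Sult1a1 in that list was at 23.1 ± 7.20 FPKM against 6.60 ± 1.05 FPKM (adjusted p = 0.0569). The camera adjusted p of that list was 0.177. With each of the 6 libraries left out in turn, the adjusted p of Relb ranged from 0.0519 to 0.127 and that of Ddit4 from 0.0858 to 0.334. That of Nfkb2 ranged from 0.0485, without control replicate 2, to 0.105, without 6 h replicate 1, and that of Lcn2 was 0.0564 and 0.0547 without 6 h replicates 1 and 2.

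The genes with the lowest log2 fold changes at 6 h included H2-Ab1, an MHC class II chain, at 4.64 ± 0.889 FPKM against 63.8 ± 0.935 FPKM in control (adjusted p = 0.00763). H2-DMb1, a class II loading chain, had a log2 fold change of -1.51 ± 0.17. Without control replicates 1 and 2 and 6 h replicates 1 and 2 in turn, the adjusted p of H2-Ab1 was 0.0685, 0.0562, 0.12 and 0.0789, and with each of the 6 libraries left out that of H2-DMb1 ranged from 0.052 to 0.207. Igfbp5, an insulin-like growth factor binding protein, had a log2 fold change of -1.60 ± 0.14 and Plat, tissue plasminogen activator, of -1.33 ± 0.20. With each of the 6 libraries left out, the adjusted p of Plat ranged from 0.114 to 0.296 and that of Mrc1, a macrophage marker, from 0.143 to 0.282. Plat did not pass with quantile normalization (adjusted p = 0.0639). The adjusted p of Igfbp5 was 0.0877, 0.0675, 0.0881 and 0.0872 without 6 h replicates 1 and 2 and 24 h replicates 1 and 2. Of the 15 macrophage and monocyte markers, 1 rose (the endotoxin co-receptor gene Cd14, chosen after its value was seen) and 1 fell, the mannose receptor gene Mrc1, from 6.57 ± 0.286 to 3.50 ± 0.219 FPKM. The list median was -0.31 (camera adjusted p = 0.00259; adjusted p = 0.646 with an estimated correlation). Ccr2 and Csf1r had log2 fold changes of -0.94 ± 0.20 and -0.43 ± 0.09 that did not pass. None of the 12 T and NK cell markers passed in the test over all genes (0 higher, 0 lower; 5 lower adjusted over the list alone). Their median was -0.63 and the camera adjusted p 0.000732 (adjusted p = 0.646 with an estimated correlation). Cd3g was at 0.510 ± 0.379 FPKM against 2.39 ± 0.472 FPKM, Nkg7 at 2.09 ± 0.369 against 4.21 ± 0.809 FPKM, and Lck at 0.142 ± 0.0534 against 1.10 ± 0.0434 FPKM.

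The 12 fibroblast markers (median -0.48, camera adjusted p = 0.000429), the 11 endothelial markers (-0.39, 0.00982), the 15 markers of other ductal epithelium (-0.30, 0.0201) and the 18 cholesterol synthesis genes (-0.24, 0.0275) lay lower than other genes, with 0 members passing in any of the 4 lists. Adjusted over the list alone, 6, 0, 3 and 0 members were lower. With an estimated correlation the adjusted p was 0.706, 0.778, 0.778 and 0.778 in the same order. Among them, the collagen gene Col3a1 had a log2 fold change of -1.22 ± 0.22, Lum of -0.83 ± 0.17 and Col1a1 of -0.72 ± 0.15. The endothelial genes Emcn, Kdr and Tie1 were at -0.51 ± 0.15, -0.57 ± 0.19 and -0.42 ± 0.18, and the sodium channel subunit genes Scnn1g, Scnn1b and Scnn1a at -1.20 ± 0.26, -0.90 ± 0.21 and -0.56 ± 0.14. The cholesterol synthesis genes Pmvk and Fdps were at -0.42 ± 0.13 and -0.45 ± 0.15. Single libraries moved such values: Fdps was at -0.644 and -0.262 without control replicates 1 and 2 in turn. Emcn was at -0.334 and -0.686 without 6 h replicates 1 and 2 in turn. The 15 acinar markers lay higher (median 0.26, camera adjusted p = 0.0286; adjusted p = 0.706 with an estimated correlation), with Lpo at 0.37 ± 0.12 and Tcn2 at 0.26 ± 0.11. Smgc was listed at 0 in control replicate 1, and was at 251 FPKM in control replicate 2 and 304 and 541 FPKM at 6 h. The mean of the acinar list was 1.73. Its members Dcpp1, Dcpp2 and Dcpp3 were at 3.15, 1.33 and 3.72 FPKM in control replicate 1 and at 6345, 14822 and 17205 FPKM in control replicate 2. How far control replicate 1 alone gives the acinar list call was not tested.

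No member passed among the fluid secretion machinery genes (20 tested, median 0.12, camera adjusted p = 0.261), the interferon-stimulated genes (33, 0.14, 0.0619, or 0.00026 without 6 h replicate 1), the DNA replication genes (23, -0.09, 0.258) or the G2/M and mitosis genes (6, -0.07, 0.68). The water channel gene Aqp5 was at 147 ± 5.39 FPKM against 135 ± 29.4 FPKM and the muscarinic receptor gene Chrm3 at 5.66 ± 1.05 against 5.15 ± 0.714 FPKM (adjusted p = 0.742 and 0.818). Mki67, a proliferation gene, was under the filter, at 0.810, 0.586 and 0.711 FPKM in control, 6 h and 24 h glands. The camera adjusted p was 0.322 for DNA damage signalling and repair genes, 0.77 for immediate early genes and for heat shock protein genes, 0.65 for unfolded protein response genes, 0.467 for NRF2 and oxidative stress genes and 0.348 for ribosomal protein genes. Among marker lists it was 0.322 for granular convoluted tubule markers, 0.0873 for basal and myoepithelial markers, 0.49 for plasma cell markers, 0.799 for adipocyte markers and 0.68 for skeletal muscle markers. The median and the camera direction differed in sign for the G2/M and heat shock lists. The number of genes called at 6 h fell from 118 to 31, 59, 12, 7, 29 and 30 when control replicates 1 and 2, 6 h replicates 1 and 2, and 24 h replicates 1 and 2 were left out in turn. In the same order 9, 8, 14, 16, 9 and 9 of the 22 called genes named here then no longer passed. With control replicate 1 and 24 h replicate 2 both left out, a fit chosen after seeing the data, limma called 0 genes (1275 at an unadjusted p under 0.05). Without the expression filter it called 68, and in a fit of the 2 groups alone 31.

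The second comparison asked which genes differed 24 h after irradiation. Interferon-stimulated genes, macrophage markers, NF-kB genes and p53 targets were higher at 24 h, and Egf and several kallikrein genes of the granular convoluted tubule were lower. With an estimated correlation none of these list calls held (adjusted p = 0.157 for p53 targets and 0.545 for the other lists). Fry called p53 targets (adjusted p = 0.000442), interferon-stimulated genes (0.0126), macrophage markers (0.0126) and NF-kB genes (0.0149) higher. Fry does not set a list against the other genes, and it gave the granular convoluted tubule list the opposite direction, up. For p53 targets the estimated correlation was 0.004, under the 0.01 of the main test, so a higher correlation does not explain the loss of that call. At 6 h their unadjusted camera p rose from 9.64e-36 to 0.000853 at the same estimate. Camera values with an estimated correlation therefore do not measure correlation between genes alone, in any comparison. The interferon-induced GTPase gene Gbp2 was at 36.2 ± 4.74 FPKM at 24 h against 6.58 ± 1.32 FPKM in control (SD, n = 2), a log2 fold change of 2.30 ± 0.17. The growth factor gene Egf was at 967 ± 80.9 FPKM against 6283 ± 1469 FPKM, a log2 fold change of -2.68 ± 0.21. The form of the values points to another quantification route for the 24 h columns than for the control columns, so the route and the time cannot be told apart in any 24 h comparison, the gene groups that follow included. Limma called 2451 genes higher and 502 lower at an adjusted p under 0.05, 717 and 269 of them by at least 2-fold. The median log2 fold change of all genes was 0.20 as deposited and -0.03 with median-of-ratios factors. The split was 1091 higher and 970 lower with those factors, and 987 and 942 with quantile normalization. In the same order 16 and 21 of the 73 called genes named here no longer passed. The count of calls fell from 2953 to 1753, 1295 and 1266 without control replicate 1, 24 h replicate 1 and 24 h replicate 2, and 16, 20 and 17 of the 73 called genes named here then no longer passed. Without control replicate 2, 14 no longer passed. The count fell to 316 with control replicate 1 and 24 h replicate 2 both left out, a fit chosen after seeing the data.

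Of the 36 p53 target genes, 28 rose and 0 fell at 24 h (31 and 0 adjusted over the list alone). Their median log2 fold change was 1.13 and the camera adjusted p 2.06e-09 (adjusted p = 0.157 with an estimated correlation). Cdkn1a was at 35.9 ± 0.431 FPKM (log2 fold change 3.51 ± 0.10), Gdf15 at 21.6 ± 0.325 FPKM (3.92 ± 0.15) and Ccng1 at 187 ± 2.17 FPKM (2.18 ± 0.09). Bax rose by 2.07 ± 0.16 and Phlda3 by 1.99 ± 0.11 on the log2 scale. Mdm2 and Bbc3 passed as deposited, with log2 fold changes of 0.45 ± 0.10 and 0.77 ± 0.18, and did not pass with median-of-ratios factors (adjusted p = 0.241 and 0.0879). The calls of Ddit4, Sesn1, Perp, Ei24 and Apaf1 of this list, named for this loss, were lost with each of the other 2 scalings. Of the 24 DNA damage signalling and repair genes, 2 rose, or 1 with either of the other 2 scalings (Rnf8, a ubiquitin ligase, by 1.64 ± 0.15 and Xrcc4, an end-joining factor, by 0.77 ± 0.18), and Xrcc6 was at 0.43 ± 0.13 (list camera adjusted p = 0.824).

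Of the 33 interferon-stimulated genes, 24 rose and 0 fell (29 and 0 adjusted over the list alone). Their median was 1.04 and the camera adjusted p 6.77e-08 (adjusted p = 0.545 with an estimated correlation). Gbp3 rose by 1.86 ± 0.12 and the tethering factor gene Bst2 from 21.9 ± 0.869 to 87.7 ± 4.22 FPKM. The calls of Stat2, Ifih1, Rtp4, Xaf1, Cmpk2 and Ifi35, named for this loss, were lost with each of the other 2 scalings. Of the 15 macrophage and monocyte markers, 11 rose and 0 fell, or 6 and 0 with either of the other 2 scalings (median 0.96, camera adjusted p = 0.00048; adjusted p = 0.545 with an estimated correlation). They included the complement genes C1qc (1.71 ± 0.15) and C1qa (1.20 ± 0.14) and Mpeg1, a perforin-like gene (1.27 ± 0.13). Of the 16 inflammatory cytokine and NF-kB genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.94, camera adjusted p = 0.00187; adjusted p = 0.545 with an estimated correlation). With median-of-ratios factors and quantile normalization 7 and 5 of them rose. They included the NF-kB inhibitor gene Nfkbia (0.90 ± 0.13), the adhesion gene Vcam1 (2.1 ± 0.30) and Csf1, a macrophage growth factor (0.89 ± 0.12). Of the 12 T and NK cell markers, 4 rose, with Nkg7 at 1.35 ± 0.15, Lck at 1.17 ± 0.20 and Cd3g at 1.09 ± 0.21 (median 1.05, camera adjusted p = 0.193). The B cell gene Ms4a1 was at 0.0920 and 2.82 FPKM in 24 h replicates 1 and 2.

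**Figure D3:**
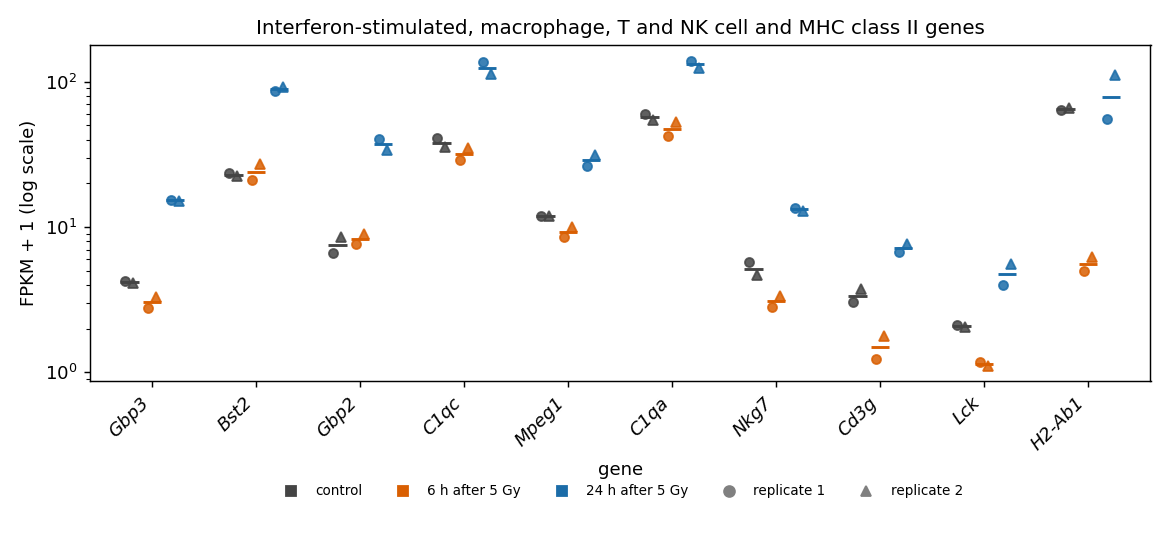
FPKM + 1 on a log axis for interferon-stimulated (Gbp3, Bst2, Gbp2), macrophage (C1qc, Mpeg1, C1qa), T and NK cell (Nkg7, Cd3g, Lck) and MHC class II (H2-Ab1) genes, 1 point per library and a line at the geometric mean of FPKM + 1. Bst2 was at 21.9, 23.1 and 87.7 FPKM in control, 6 h and 24 h glands (means, n = 2), and H2-Ab1 at 63.8, 4.64 and 81.9 FPKM.

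Of the 21 granular convoluted tubule markers, 11 fell and 3 rose at 24 h, with a median of -0.90 and a camera adjusted p of 8.15e-06 (adjusted p = 0.545 with an estimated correlation). Fry gave the opposite direction, up, with an adjusted p of 0.0209, and with quantile normalization 5 fell and 2 rose. Ren1, the renin gene, and Klk1 rose, as did Klk1b26 (Ren1 and Klk1 chosen after their values were seen), though Klk1 did not pass with either of the other 2 scalings (adjusted p = 0.0783 and 0.0822). The median and the mean of the list differed in sign, with a mean of 0.39 that includes Klk1b26. That gene was at 0.186 and 0.194 FPKM in control and 21402 and 23310 FPKM at 24 h. The kallikrein genes Klk1b27 and Klk1b8 had log2 fold changes of -2.09 ± 0.25 and -1.67 ± 0.21. Both belong to a family of closely similar genes among which reads are hard to assign, so single members are uncertain. The 14 family genes summed to 107338 and 78151 FPKM in control and 88460 and 78116 FPKM at 24 h. Their sum was 67059 and 54807 FPKM at 24 h without Klk1b26.

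Of the 18 clock genes, 12 rose and 2 fell (median 1.28, camera adjusted p = 0.0336; adjusted p = 0.696 with an estimated correlation). Dbp was at 33.5 ± 3.31 FPKM, Tef at 53.9 ± 7.64 FPKM and Ciart at 6.25 ± 0.475 FPKM, and Arntl fell to 0.754 ± 0.306 FPKM (log2 fold change -2.76 ± 0.17). The calls of Cry1, Per1 and Nr1d1, named for this loss, were lost with each of the other 2 scalings.

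**Figure D4:**
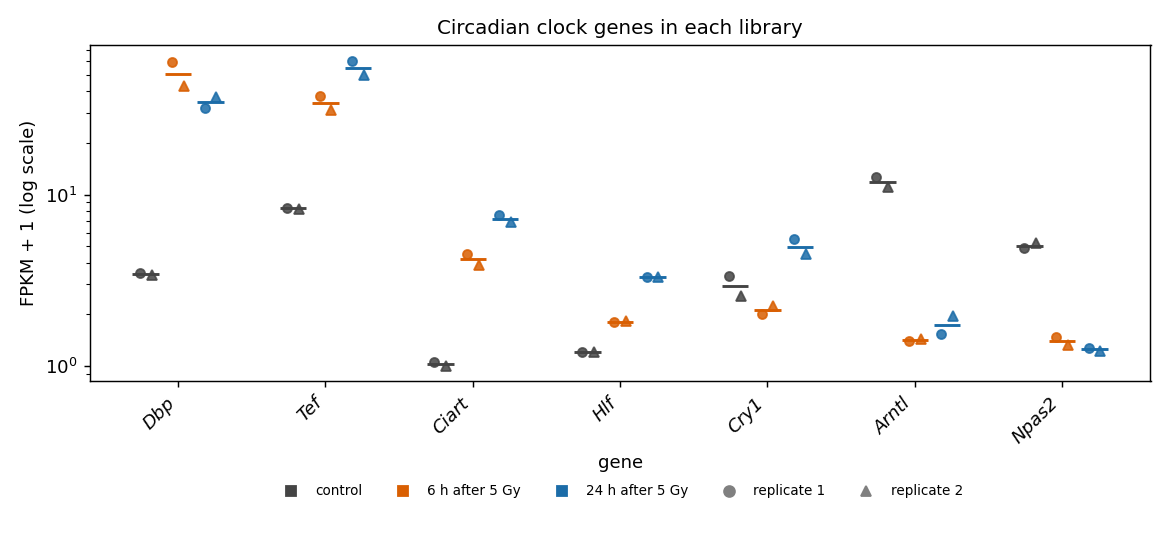
FPKM + 1 on a log axis for 7 clock genes in the 6 libraries, with a line at the geometric mean of FPKM + 1 of each group. Arntl was at 10.8 FPKM in control, 0.417 FPKM at 6 h and 0.754 FPKM at 24 h (means, n = 2).

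The ribosomal protein list had 27 of 28 members higher at 24 h, or 17 with median-of-ratios factors and 2 with quantile normalization (median 0.80, camera adjusted p = 2.06e-09; adjusted p = 0.545 with an estimated correlation), and its median was -0.07 with quantile normalization. Rps18 and Rps14 had log2 fold changes of 1.77 ± 0.10 and 1.53 ± 0.14. Rpl30 was at 0.129 FPKM in control replicate 1, listed at 0 in control replicate 2, and at 16.1 and 18.9 FPKM at 24 h. Many of the most extreme values at 24 h were of this kind. Rps27rt, Rpl34-ps1, Atp6v0c, Oaz1 and Ndufs5 were listed at 0 in the 4 control and 6 h libraries and at 3119, 373, 140, 101 and 75.7 FPKM in 24 h replicate 1. Spt1, the most abundant transcript of the control glands at 226660 and 227930 FPKM, was listed at 0 in both 24 h libraries, as was AF357359. Plet1os, Sycp3, AV051173 and LOC100503496 were at 0.390, 0.396, 0.236 and 0 FPKM in 24 h replicate 1 against 297, 19.5, 46.2 and 22.9 FPKM in control replicate 1.

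Among the other lists, 6 of 20 fluid secretion machinery genes rose and 0 fell, or 1 and 1 with either of the other 2 scalings (median 0.19, camera adjusted p = 0.952), with Itpr3, a calcium release channel, at 0.62 ± 0.11. The potassium channel genes Kcnn4 and Kcnma1 were at 0.57 ± 0.10 and 0.92 ± 0.17, and the list median was -0.05 with median-of-ratios factors and -0.18 with quantile normalization. Aqp5 and Chrm3 had log2 fold changes of 0.49 ± 0.16 and 0.02 ± 0.16 that did not pass (adjusted p = 0.0649 and 0.937). Of 14 heat shock protein genes 6 rose, or 4 with median-of-ratios factors and 2 with quantile normalization (Hspe1 0.90 ± 0.09, Hspa8 0.86 ± 0.10 and Hsp90aa1 0.68 ± 0.10; camera adjusted p = 0.0585). The glucocorticoid and systemic stress response list had 6 of 16 higher, or 4 and 3 in the same order (Lcn2 0.90 ± 0.09, and the metallothionein genes Mt1 1.14 ± 0.11 and Mt2 1.34 ± 0.18; camera adjusted p = 0.527). The NRF2 list had 4 of 19 higher and 0 lower, or 1 and 1 with median-of-ratios factors and 2 and 2 with quantile normalization (Txnrd1 0.72 ± 0.14, the heme oxygenase gene Hmox1 2.0 ± 0.42 and Prdx1 0.54 ± 0.13; camera adjusted p = 0.952). The unfolded protein response list had 3 of 25 higher and 1 lower as deposited (Xbp1 0.58 ± 0.13, Herpud1 0.49 ± 0.11 and Asns 0.50 ± 0.12 higher, Dnajb9 lower; camera adjusted p = 0.102). The direction of its calls turned to 0 higher and 7 lower with median-of-ratios factors, and 0 and 8 with quantile normalization. With quantile normalization the log2 fold changes of Prdx1, Xbp1 and Herpud1 were -0.05, -0.02 and -0.03.

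Immediate early genes lay lower than other genes (23 tested, 3 higher and 1 lower, or 1 and 2 with either of the other 2 scalings; median -0.14, camera adjusted p = 0.0213; adjusted p = 0.545 with an estimated correlation; fry adjusted p = 0.907). Gadd45b, Nr4a1 and Ier5 rose by 1.13 ± 0.18, 0.54 ± 0.13 and 0.79 ± 0.20, and Maff fell. Cholesterol synthesis genes also lay lower (18 tested, median -0.10, camera adjusted p = 0.0213; adjusted p = 0.9 with an estimated correlation; fry adjusted p = 0.741). Sc5d was lower at -1.75 ± 0.13 and Pmvk higher at 0.59 ± 0.13, the latter not passing with either of the other 2 scalings, with Dhcr7 and Cyp51 at -0.32 ± 0.16 and -0.40 ± 0.22, neither passing. Skeletal muscle genes lay higher, with 5 of 7 passing, or 3 with quantile normalization (Mylpf 1.41 ± 0.20, Tnnc2 1.73 ± 0.30 and Tnnt3 1.51 ± 0.26; camera adjusted p = 0.0336; adjusted p = 0.545 with an estimated correlation). Among epithelial markers, the acinar genes Tcn2 and Scgb2b26 rose by 0.84 ± 0.11 and 1.86 ± 0.37 and Pip was at 0.96 ± 0.29 without passing. Ascl3, Fxyd2 and Kit of the ductal list rose by 1.93 ± 0.16, 2.31 ± 0.27 and 0.48 ± 0.11, and Krt18 fell. Krt5 and Trp63 of the basal list rose by 1.10 ± 0.16 and 0.85 ± 0.17, Krt14 was at 0.65 ± 0.21 without passing, and the epidermal gene Krt10 was at 10.7 and 129 FPKM in the 24 h libraries. The camera adjusted p was 0.952, 0.824 and 0.366 for these 3 lists. As deposited 2 acinar, 4 ductal and 2 basal markers were higher and 0, 1 and 0 lower, and with quantile normalization 0, 2 and 1 were higher and 0, 2 and 3 lower. In the replication list Pold1 rose by 0.60 ± 0.13, Mcm2 and Mcm6 were at 0.51 ± 0.17 and 0.91 ± 0.31 without passing, and Gins2 fell (camera adjusted p = 0.712). In the G2/M list Spc25 rose by 0.70 ± 0.13, Ube2c and Cks2 were at 0.49 ± 0.30 and 0.36 ± 0.23, and Kif20a fell (camera adjusted p = 0.532). Dnajb9, Maff, Krt18, Gins2 and Kif20a were chosen after their values were seen. Endothelial and fibroblast markers had 0 members passing (medians 0.27 and 0.21, the latter -0.02 with median-of-ratios factors; camera adjusted p = 0.952 for each), and adipocyte and plasma cell markers had camera adjusted p of 0.813 and 0.952. The median and the camera direction differed in sign for the DNA damage, replication, G2/M, NRF2, acinar, ductal, fibroblast and adipocyte lists, and the median and the mean for the unfolded protein response, basal and granular convoluted tubule lists. With median-of-ratios factors the medians of the DNA damage, G2/M, NRF2 and ductal lists were -0.09, -0.07, -0.11 and -0.12, against 0.08, 0.12, 0.16 and 0.13 as deposited. Of the genes given as higher at 24 h, Bbc3, Mdm2, Xrcc4, Itpr3, Kcnn4, Prdx1, Xbp1, Herpud1, Asns, Nr4a1, Ier5, Pmvk, Kit, Trp63, Pold1, Spc25 and Klk1 did not pass with either of the other 2 scalings. Txnrd1 did not pass with median-of-ratios factors, nor Hsp90aa1, Hspa8, Mt1, Rps14, Scgb2b26 and Tcn2 with quantile normalization.

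The third comparison, 24 h against 6 h, tested whether the effects at the 2 times differed. It carried the same apparent difference of route. Limma called 2734 genes higher and 503 lower at 24 h (1249 and 1106 with median-of-ratios factors; 1148 and 1047 with quantile normalization). In the same order 15 and 19 of the 73 called genes named here no longer passed. The count of 3237 fell to 1415, 1905, 1481 and 1489 without 6 h replicates 1 and 2 and 24 h replicates 1 and 2, and 21, 11, 23 and 20 of the 73 called genes named here then no longer passed. It fell to 806 with control replicate 1 and 24 h replicate 2 both left out. Gdf15 was lower at 24 h than at 6 h, with a log2 fold change of -1.65 ± 0.15, as were Mdm2 (-0.65 ± 0.10) and Dcxr, a carbonyl reductase (-0.63 ± 0.11). Of the 36 p53 targets 5 were higher and 7 lower as deposited, 3 and 15 with median-of-ratios factors, and 2 and 13 with quantile normalization (median -0.18, camera adjusted p = 0.000515; adjusted p = 0.624 with an estimated correlation; fry adjusted p = 0.651). Cdkn1a, Bax, Bbc3, Phlda3 and Ccng1 had log2 fold changes of -0.23 ± 0.10, -0.04 ± 0.16, 0.03 ± 0.18, 0.07 ± 0.11 and -0.26 ± 0.09 that did not pass; with median-of-ratios factors the log2 fold changes of Cdkn1a and Ccng1 passed, at -0.52 and -0.56, as they did with quantile normalization, at -0.56 and -0.94.

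The interferon-stimulated genes were higher at 24 h than at 6 h (22 of 33 higher, or 14 with either of the other 2 scalings, 0 lower, median 1.12, camera adjusted p = 1.91e-05; adjusted p = 0.687 with an estimated correlation). So were macrophage markers (13 higher, 1 lower of 15; median 1.20, camera adjusted p = 0.000167; adjusted p = 0.687 with an estimated correlation) and the T and NK cell markers (9 of 12 higher, or 5 with either of the other 2 scalings; median 1.44, camera adjusted p = 0.00817; adjusted p = 0.687 with an estimated correlation). H2-Ab1 rose from 4.64 ± 0.889 to 81.9 ± 39.2 FPKM and was at 63.8 ± 0.935 FPKM in control. The NF-kB list went both ways (7 higher and 3 lower of 16, or 3 and 3 with either of the other 2 scalings; camera adjusted p = 0.8). Ccl3, Vcam1 and Ccl2 were higher by 1.26 ± 0.20, 1.77 ± 0.30 and 2.19 ± 0.39, and Relb and Nfkb2 had log2 fold changes of -1.21 ± 0.25 and -0.67 ± 0.10. Birc3 was also lower at 24 h, and Cd14 was the macrophage marker that was lower, both chosen after their values were seen. Fibroblast markers were higher in 7 of 12, or 4 with either of the other 2 scalings (Lum 1.32 ± 0.17, Col1a1 1.01 ± 0.15, Col1a2 0.90 ± 0.14; camera adjusted p = 0.0905). Endothelial markers were higher in 5 of 11, or 1 with either of the other 2 scalings, in which Eng and Plvap did not pass (Emcn 1.0 ± 0.15, Eng 0.83 ± 0.20, Plvap 1.01 ± 0.24; camera adjusted p = 0.168). Granular convoluted tubule markers were lower in 11 of 21 and higher in 3 (median -0.83, camera adjusted p = 3.12e-05; adjusted p = 0.687 with an estimated correlation). For this list too fry gave the direction up (adjusted p = 0.0187), and with quantile normalization 4 were lower and 3 higher. Ribosomal protein genes were higher in 25 of 28, or 16 with median-of-ratios factors and 2 with quantile normalization (median 0.78, camera adjusted p = 5.45e-08; adjusted p = 0.687 with an estimated correlation; median 0.01 with quantile normalization) and skeletal muscle genes in 4 of 7 (camera adjusted p = 0.0322; adjusted p = 0.687 with an estimated correlation). Among other lists, Fxyd2 and Ascl3 of the ductal list (2.85 ± 0.27 and 1.42 ± 0.16) and the clock genes Cry1 and Hlf (1.23 ± 0.19 and 0.86 ± 0.15) were higher at 24 h than at 6 h. So were Hspe1 and Hsp90aa1 (1.13 ± 0.09 and 0.70 ± 0.10) and Mcm6, Dut and Gins1 of the replication list (1.40 ± 0.31, 0.51 ± 0.13 and 0.68 ± 0.17). Gpx1 and Txnrd1 of the NRF2 list (0.74 ± 0.11 and 0.76 ± 0.14) and Atp1b1 of the fluid secretion list (0.58 ± 0.12) were higher too. With quantile normalization Atp1b1 and Tcn2 turned to -0.22 and -0.11, and Gpx1, Hlf and Hsp90aa1 did not pass. Atp1b1, Dut and Gins1 did not pass with either of the other 2 scalings, nor Txnrd1 with median-of-ratios factors. Maff and Atf3 were lower (-0.95 ± 0.15 and -0.54 ± 0.12). Their camera adjusted p was 0.339, 0.624, 0.112, 0.8, 0.685, 0.8 and 0.167, in the order ductal, clock, heat shock, replication, NRF2, fluid secretion and immediate early. Medians of the DNA damage, G2/M, immediate early, unfolded protein response, NRF2, fluid secretion, basal, cholesterol and plasma cell lists changed sign with 1 or both of the other scalings. The largest positive and negative values were those of the genes listed at or near 0 by one route, which included Tgoln1, at 0 in both 24 h libraries and at 13.9 and 23.7 FPKM at 6 h.

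Of the genes called at 6 h, 69 were called higher and 10 lower at 24 h against control as well, and 11 were called in opposite directions. Independent lists of these sizes would share 17 higher and 1.6 lower genes. The 2 sets of log2 fold changes correlated at 0.18, against 0.5 in 100 simulations of unchanged groups against the shared controls, and their covariance was 0.05, against 0.053 simulated, a difference of -0.004. The simulated groups shared 0 calls, which does not measure what shared controls add to lists of this size. The controls could not be split because each part would hold 1 library, so part of the overlap may come from the shared controls. By the tests of the differences, 57 genes had a sustained change, called in the same direction at both times and not between them (49 higher, 8 lower), among them Cdkn1a, Bax, Ccng1, Phlda3, Aen, Eda2r, Dbp, Arntl and Npas2. With either of the other 2 scalings Cdkn1a, Ccng1 and Dbp were lower at 24 h than at 6 h and left this class, as did Aen with median-of-ratios factors. The class called transient, in which a 6 h change was followed by a called change in the opposite direction from 6 h to 24 h, held 54 genes (26 higher and 28 lower at 6 h). It does not mean a return to control: 28 of the 54 were not called at 24 h against control, 15 were still called in the direction of 6 h and 11 in the opposite direction. In this class Gdf15 and Lcn2 were still higher than control at 24 h, Igfbp5 was lower at 6 h and higher at 24 h, and H2-Ab1, H2-DMb1 and Plat did not pass at 24 h. Mdm2, Relb, Nfkb2 and Mrc1 were called higher than control at 24 h as deposited, and did not pass with either of the other 2 scalings. A late change was called for 2196 genes (1832 higher, 364 lower), or 1455 with median-of-ratios factors. These genes differed at 24 h from both other groups, which another quantification route for the 24 h columns would also give. Route and time cannot be told apart for this class.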

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

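The tests of the route as a whole, of matched random lists, of the epithelial share and of the clock arms were chosen after the results were seen; those of exon length and overlapping exons were set before. The effects at 6 h and at 24 h, both against control, differed by the test of 24 h against 6 h in 3237 genes. At 24 h against 6 h camera, which sets a list against the other genes, called p53 targets (median -0.18) and interferon-stimulated genes (1.12). Medians of the other called lists were 0.78 (ribosomal protein), -0.83 (granular convoluted tubule), 1.20 (macrophage), 1.44 (T and NK cell) and 1.33 (skeletal muscle). The median of all genes was 0.22. Fry, which tests the members themselves, did not call p53 targets (adjusted p = 0.651, 5 higher and 7 lower). It called the other 6 lists, each with the direction up, against the median for the tubule list (adjusted p = 0.0187). For the others fry's adjusted p was 0.0175 (interferon-stimulated, T and NK cell, skeletal muscle) and 0.00913 (ribosomal protein, macrophage). With an estimated correlation camera's adjusted p was 0.624 for p53 targets and 0.687 for the other 6 lists.

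Of 143 named genes tested, 88 had effects that differed between 6 h and 24 h (72 higher and 16 lower at 24 h). Another 11 were left out because all libraries of one route listed them under 0.2 FPKM. Many of the 88 were named for their rank in this same test, so their count is no separate result. Of all genes tested 27.7% were called, and 84.5% of those calls were higher. Values given here are the log2 fold change of 24 h against 6 h. Among p53 targets it was Gdf15 -1.65, Mdm2 -0.65 and Dcxr -0.63. Interferon-stimulated genes had Bst2 1.89, Gbp2 2.16 and Gbp3 2.33. Chemokine, adhesion and NF-kB genes had Ccl2 2.19, Ccl3 1.26, Csf1 0.45, Vcam1 1.77, Nfkb2 -0.67 and Relb -1.21. Macrophage markers had C1qa 1.48, C1qc 1.97, Ccr2 1.20, Csf1r 0.88, Mpeg1 1.64 and Mrc1 1.14, and T and NK cell markers Cd3g 2.28, Lck 2.05 and Nkg7 2.11. MHC class II genes had H2-Ab1 3.80 and H2-DMb1 1.88. Clock genes had Ciart 0.79, Cry1 1.23, Hlf 0.86 and Tef 0.68. Stress response and immediate early genes had Lcn2 -0.45, Mt1 0.85, Mt2 0.68, Sgk1 1.04, Sult1a1 -1.21, Tsc22d3 1.42, Atf3 -0.54 and Maff -0.95. Heat shock and unfolded protein response genes had Hsp90aa1 0.70, Hspa1a 0.74, Hspa8 0.45, Hspe1 1.13, Dnajb11 0.70, Herpud1 0.39, Sdf2l1 0.84 and Sec61b 0.82. Oxidative stress genes had Gpx1 0.74, Prdx1 0.64 and Txnrd1 0.76, and cholesterol synthesis genes Pmvk 1.01 and Sc5d -1.44. Repair and replication genes had Rnf8 1.72, Xrcc4 0.89, Dut 0.51, Gins1 0.68, Mcm2 0.61 and Mcm6 1.40. Fluid secretion genes had Atp1b1 0.58 and Itpr3 0.39, and ribosomal protein genes Rps14 1.43 and Rps18 1.74. Epithelial markers had Scgb2b26 2.67, Tcn2 0.58, Egf -2.42, Klk1b27 -1.94, Klk1b8 -1.80, Ascl3 1.42, Fxyd2 2.85, Kit 0.78, Scnn1a 1.10, Scnn1b 0.81, Scnn1g 1.33, Krt5 1.36 and Trp63 1.22. Endothelial markers had Emcn 1, Eng 0.83, Kdr 0.79 and Plvap 1.01, and fibroblast markers Col1a1 1.01, Col1a2 0.90, Col3a1 1.08 and Lum 1.32. Skeletal muscle genes had Mb 1.43, Mylpf 1.77, Tnnc2 1.77 and Tnnt3 1.33. The other genes were Igfbp5 2.58, Plat 1.25, AV051173 -5.17, Plet1os -7.60 and Sycp3 -4. With median-of-ratios factors 65 of the 88 passed (49 higher and 16 lower), and with quantile normalization 60 (44 and 16). Atp1b1, Ciart, Csf1, Dnajb11, Dut, Eng, Gins1, Herpud1, Hspa1a, Hspa8, Itpr3, Kdr, Mcm2, Mt2, Plvap, Prdx1, Scnn1b, Sdf2l1, Sec61b, Tcn2, Tef and Xrcc4 passed with neither. Txnrd1 did not pass with the first alone, nor Gpx1, Hlf, Hsp90aa1, Mt1, Rps14 and Scgb2b26 with the second alone. With quantile normalization Atp1b1, Herpud1, Hspa8 and Tcn2 turned to -0.22, -0.19, -0.305 and -0.11.

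Many more genes differed from control at 24 h than at 6 h (2953 against 118). After the trend with exon length was removed, 2661 genes were still called at 24 h, 2579 of them called before, which argues against length as the whole cause. Among the 7675 genes whose exons overlap no other gene 23.7% were called, against 28.3% of the 3597 with an overlap, which argues against another handling of overlapping genes as the whole cause. The quantification route as a whole and the time after irradiation cannot be told apart, since 0 groups hold libraries with values of both forms. A response to irradiation at 24 h therefore stays open beside the route.

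Macrophage and interferon-stimulated genes were higher at 24 h than in control. The lower of the 2 list percentiles among 10000 random lists of like expression and exon length was 99.99, which argues against a shift shared by genes of like level and length. Random genes carry none of the correlation within these lists, estimated at 0.295 for interferon-stimulated and 0.142 for macrophage genes. Adipocyte markers also reached 99.98 with 0 of 8 called, so such a percentile alone does not mark a called change. The median of 15 macrophage markers was 0.72 higher than that of 23 fibroblast and endothelial markers (permutation p = 2e-05, two-sided, across genes, which are not independent replicates), which argues against a lower share of epithelial cells as the whole cause. The test takes fibroblast and endothelial markers as a steady reference, and both lists lay lower at 6 h (medians -0.48 and -0.39). A lower epithelial share as part of the cause stays open. The route, more immune cells, more expression per cell and more neighbouring tissue may each contribute, and none of these was told apart. In 24 h replicates 1 and 2 the skin gene Krt10 was at 10.7 and 129 FPKM and the B cell gene Ms4a1 at 0.0920 and 2.82 FPKM. For the macrophage and interferon-stimulated lists camera's adjusted p with an estimated correlation was 0.545 each, and fry's adjusted p was 0.0126 each.

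Clock genes differed from control at both times. The median of 10 output genes minus that of 4 activator genes was 3.11 at 6 h and 3.51 at 24 h against control, in log2 units. If clock hour were the cause and the 24 h glands had been taken at the hour of the controls, the 24 h difference would fall well under that at 6 h, which 3.51 argues against. Controls taken at another hour than both irradiated groups could give the 3.11 at 6 h, and this cannot be told apart from an effect of irradiation because the hours are not given. The 24 h value also carries the apparent difference of route.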

How the results depend on the processing

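Leaving out control replicate 1 with 24 h replicate 2, keeping genes above 0 in every group and removing the exon length trend were alternatives chosen after the data were seen. The counts of 118 (6 h against control), 2953 (24 h against control) and 3237 genes (24 h against 6 h) stayed within 1.5 times except as follows. With 1 library left out, where the lone library of a group is assumed to vary like the others, they ranged from 7 to 59, 1266 to 2345 and 1415 to 3259. With control replicate 1 and 24 h replicate 2 both left out, which leaves 4 libraries and 1 residual degree of freedom, limma called 0 (1275 at an unadjusted p under 0.05), 316 and 806. At 6 h the count was 68 with no filter, 31 with only the 2 groups compared and 240 at an adjusted p under 0.1. At 24 h it was 1929 with quantile normalization, and with a minimum absolute log2 fold change of 1 it was 986 against control and 1102 against 6 h. Late time courses numbered 1455 with median-of-ratios factors against 2196. A lower count with fewer libraries or a stricter threshold follows from the setting; for the other settings the cause was not tested.

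With an estimated correlation, camera's adjusted p was 0.646 for inflammatory cytokine and NF-kB genes at 6 h against control; 0.157, 0.545 and 0.545 for p53 targets, NF-kB and interferon-stimulated genes at 24 h against control; and 0.624 and 0.687 for p53 targets and interferon-stimulated genes at 24 h against 6 h. Interferon-stimulated genes at 6 h ranged from 0.00026 to 0.957 with 1 library left out. The p53 target call at 6 h held in every setting run, at most 0.0222.

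Quantile normalization turned 5 log2 fold changes of genes named for their comparison: at 24 h against control Xbp1 to -0.024, Herpud1 to -0.033 and Prdx1 to -0.045, and at 24 h against 6 h Atp1b1 to -0.218 and Tcn2 to -0.111. A change of sign between values not called in either setting was not counted. Of 22, 73 and 73 called named genes in the 3 comparisons, 0, 25 and 30 were called in every setting.

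Replicate numbers pair no samples in the labels. Deviations of like-numbered replicates correlated across genes at 0.47 (control and 6 h), 0.31 (control and 24 h) and 0.17 (6 h and 24 h), and a replicate block gave 104, 3001 and 3351 genes. With the block Plat and Mrc1 (adjusted p = 0.0721 and 0.0691, 6 h against control) and Itpr3 (0.0541, 24 h against 6 h) did not pass. Cd3g at 6 h (0.0407) and Xrcc6, Mcm6 and Krt14 at 24 h (0.0492, 0.0361 and 0.0471), both against control, did pass. The planned count-based test was not run because the 24 h columns hold no whole-read steps, and the robust variance setting was not run for lists, since camera has none. The unknown depth at 24 h leaves the precision of low values there open.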

Other observations

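Adipocyte markers had a median log2 fold change of 1.10 at 24 h against control with 0 of 8 called, and of 0.06 at 6 h. Their levels split the libraries within groups: Fabp4, a fatty acid carrier of fat cells, was at 22.4 and 399 FPKM in control, 42.7 and 282 FPKM at 6 h, and 297 and 143 FPKM at 24 h. Bpifa2, a salivary secretory protein gene, was at 5.31 and 21486 FPKM in control, 1400 and 31279 FPKM at 6 h, and 5506 and 51025 FPKM at 24 h. The neutrophil gene S100a8 was at 0 and 0.431 FPKM in control, 0 and 2.23 FPKM at 6 h, and 1.43 and 6.81 FPKM at 24 h. Fabp4, Bpifa2 and S100a8 were chosen after their values were seen.

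Other single members of lists passed at 24 h against control. Mzb1, a plasma cell gene, and Mbp, a myelin gene, were higher, with FPKM means of 16.3 ± 9.96 against 4.04 ± 1.54 and 10.4 ± 0.237 against 4.98 ± 0.495 (SD, n = 2). Alas2, the heme synthesis gene of red cells, was lower, at 1.10 ± 0.149 against 3.37 ± 1.34 FPKM. These genes were chosen after their values were seen, and the form of the values at 24 h points to another route than for control. With median-of-ratios factors or quantile normalization no plasma cell marker passed, Mzb1 included.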
